A study of Mus musculus with 6 samples.

How the data were processed

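RNA was sequenced from 6 samples of mouse 4T1 mammary carcinoma cells, 3 exposed for 24 h to nanoparticles (CM-PEG-PLGA@DOX/R848 in the labels) and 3 given phosphate-buffered saline (PBS). Per the labels' protocols, RNA was extracted with TRIzol, checked for integrity on a Bioanalyzer and made into libraries by an mRNA enrichment protocol with fragmentation and PCR. Whether the library kit marked strand is not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

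The deposited table holds FPKM values (fragments scaled by transcript length and by the mapped fragments of the library), a unit that its header does not name and that was inferred from the values. They were not whole numbers, their sums ranged from 421544 to 425231 in the PBS libraries and from 468387 to 472870 in the nanoparticle libraries, and their products with exonic length summed to nearly the same total in all 6 libraries. Per the submitters' processing notes, STAR and featureCounts were used and the builds were GRCm38 and mm10, with no version or role given for either tool. The table also held 690 features with identifiers of the kind a transcript assembler gives and 11 with transcript identifiers; the program that made the FPKM values and the annotation release are not given in the sources used here. These 701 features stayed out of the tests and made up 0.631% to 0.67% of the summed FPKM of each library. Low values were searched for steps of 1 read: between libraries of a group, at most 2.05% of the ratios of values under 0.2 FPKM fell in any 1% bin, so no read unit could be recovered, the depth of the libraries is unknown, and no counting interval is given.

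The design fixed before the data were examined put a count test first and, for a table without counts, limma-trend on log2 values. That second test is the one used. Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in 3 or more of the 6 libraries were tested, which left 10863 of 22105 features with a gene identifier. A gene under 1 FPKM in every library of one group was tested only if every library of the other reached 1 FPKM. The direction of such a gene was fixed by the filter. Each gene was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0; lmFit, then eBayes with trend and robust settings), nanoparticle minus PBS, without a replicate block. Two-sided p-values were adjusted over all tested genes by the Benjamini-Hochberg method and called at an adjusted p under 0.05. A gene was counted as changed at least 2-fold when it was called and its log2 fold change was at least 1 in size. A fold change on the log2(FPKM + 1) scale understates the change of low genes. In simulated data drawn with the spread of these libraries, 50 of the 10863 genes were changed at each fold size. The test recovered 62% of genes changed 1.25-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. It made 8 false calls among 10663 unchanged genes. Far fewer genes changed in the simulated data than were called in the real data. The recovery rates were not split by expression level, so they do not show how many low genes would be recovered.

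A set of 38 gene lists was fixed from the treatment and the cell type before the data were examined, and 34 of them had at least 5 tested members. These were tested with camera from limma (preset correlation between genes 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation and with fry. None of 29 random lists was called in the simulated data. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are falsely called. In the real data the estimated correlation reached 0.616, in the mitochondrially encoded list. Genes were named by a rule fixed at the same time: the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM and no overlap between groups, clone names left out; the 3 members of each list with the smallest adjusted p; and fixed genes set in advance by their link to the drugs, cell death, proliferation and immune recognition. A gene named outside this rule is marked as chosen after its values were seen. Of the genes this rule chose, 2 are not reported here.

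Gene positions, genomic span (gene start to gene end), exonic length and GC content were taken from GENCODE M21 (GRCm38), matched by gene identifier for 99.8% of the tested genes. Some identifiers in the table are newer than that release. Processing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The alternatives tried were a pseudocount of 0.1, no filter on low values, a threshold of 0.01, a test against a 1.5-fold change, a replicate block, each library left out in turn and mitochondrially encoded genes left out of the totals. Alternatives added after the data were seen were rescaling to TPM, median-of-ratios scaling, a filter at 5 FPKM, removal of the trend with genomic span and exonic length, and inclusion of the features without a gene identifier.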

Results

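The transcriptome of 4T1 cells, a mouse mammary carcinoma line, was measured by mRNA sequencing after 24 h with nanoparticles or with PBS. The particles, named CM-PEG-PLGA@DOX/R848 in the labels, carried doxorubicin (DOX), an anthracycline that intercalates into DNA and poisons topoisomerase II, and resiquimod (R848), an agonist of the endosomal RNA receptors TLR7 and TLR8. Their dose was equivalent to 2 µg/mL of doxorubicin. Each group had 3 libraries, and the deposited FPKM values give no depth per library. Between 10596 and 10631 genes reached 1 FPKM in each library, while genes above 0 numbered 13544 to 13808 in the PBS libraries and 18319 to 18509 in the nanoparticle libraries. Over the tested genes, Pearson's r of log2(FPKM + 1) was 0.9956 to 0.9969 within groups and 0.8617 to 0.8649 between groups.

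The comparison of nanoparticle with PBS asked which transcripts differed after exposure to the loaded particles; free drugs and empty particles were not analysed here. Most interferon-stimulated genes and most immediate early genes rose: Irf7, the master regulator of type I interferon transcription, went from 9.75 ± 0.181 to 239 ± 3.06 FPKM, and Fos, a subunit of the AP-1 transcription factor, from 2.89 ± 0.254 to 127 ± 4.48 FPKM (mean ± SD, n = 3 per group). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 14.2-fold, from 5.37 ± 0.19 to 76.3 ± 3.29 FPKM. H1f0, a linker histone of differentiated and resting cells, fell from 1062 ± 13.7 to 64.1 ± 2.13 FPKM, and Slc7a11, the cystine transporter, fell from 18.9 ± 0.336 to 0.885 ± 0.136 FPKM. Genes with a long genomic span were mostly lower.

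Among the 10 largest rises were Il24, Gadd45b, Klk10, Fos, Fosb, Btg2, Egr2, Irf7 and Egr1, with log2 fold changes from 4.47 (Egr1) to 5.69 (Il24). Il24, a cytokine of the IL-10 family at GRCm38 chromosome 1, 130882074 to 130887454, went from 0.672 ± 0.178 to 85.2 ± 2.2 FPKM (log2 fold change 5.69, standard error 0.075, adjusted p = 1.62e-11, limma). Gadd45b, a DNA damage and stress-inducible gene, went from 1.07 ± 0.141 to 69.6 ± 0.738 FPKM. Irf7 lies at chromosome 7, 141262706 to 141266481 (log2 fold change 4.48, standard error 0.028, adjusted p = 8.71e-13, limma).

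The 10 largest falls were H1f0, Fut8, Lrg1, Ptprk, Slc7a11, Ccn5, Sspn, Peak1, Hp and Mipol1, with log2 fold changes from -4.03 (H1f0) to -2.98 (Mipol1). H1f0 lies at chromosome 15, 79028450 to 79030504, and its nanoparticle mean was 0.0604 of the PBS mean (log2 fold change -4.03, standard error 0.029, adjusted p = 1.43e-12, limma). Fut8, the enzyme that adds core fucose to N-glycans, spans 238 kb at chromosome 12, 77238125 to 77476338, and went from 55.3 ± 2.98 to 3.27 ± 0.114 FPKM. Ptprk and Slc7a11 span 523 kb and 551 kb, while Lrg1 and Hp, both acute-phase genes, span 2.32 kb and 4.05 kb. Lrg1 went from 13.9 ± 0.808 to 0.208 ± 0.042 FPKM.

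**Figure D1:**
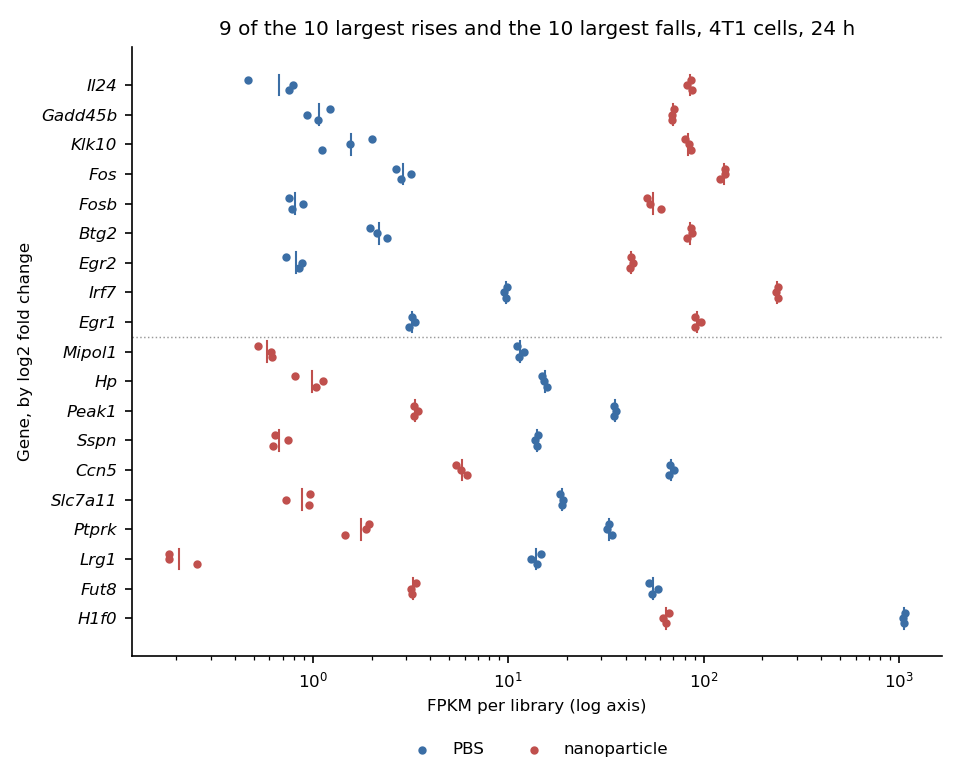
FPKM of 19 of the 20 genes with the largest rises and falls, on a log axis, with 1 point per library and a vertical bar at the mean of each group of 3 libraries (PBS blue, nanoparticle red); a dotted line parts rises from falls. The groups do not overlap for any of these genes, which the rule that chose them required.

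Of 46 tested interferon-stimulated genes, 45 rose, 43 of them at least 2-fold, 0 fell and 1 did not pass (Ifit2, log2 fold change 0.49, named after its values were seen). The median log2 fold change of this list was 2.73, and it was called by camera (adjusted p = 2.0e-16) and also with an estimated correlation (adjusted p = 0.0361 with an estimated correlation). Usp18, an ISG15 protease that restrains interferon signalling, rose from 5.04 ± 0.206 to 116 ± 2.86 FPKM, and Oasl2 rose from 10.9 ± 0.095 to 118 ± 2.16 FPKM. Ifnb1, the interferon gene fixed for naming in advance, was below the level tested. It averaged 0.126 ± 0.114 FPKM with PBS and 0.827 ± 0.366 FPKM with nanoparticles. Its libraries did not overlap, ranging from 0 to 0.221 FPKM with PBS and from 0.518 to 1.23 FPKM with nanoparticles. In the list of interferon and other cytokine ligands, 6 members were tested, of which 5 rose and 1 fell (Tslp rose by 0.66, Il23a by 0.78 and Cxcl9 by 1.94 on the log2 scale). Cxcl9 was under 1 FPKM in every PBS library, so the filter fixed its direction. The list was not called by camera (adjusted p = 0.0553), though it passed as higher on the TPM scale (0.03) and with no filter on low values (0.0392). Without any 1 of the nanoparticle libraries it had too few tested members for the test.

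The receptors of R848 were near the floor in both groups. Tlr7 averaged 0.161 ± 0.038 and 0.179 ± 0.017 FPKM, Tlr8 averaged 0.00502 ± 0.00869 and 0.114 ± 0.033 FPKM, and neither was tested. Among 17 tested TLR7 and TLR8 pathway genes, 7 rose, 9 fell and 1 did not pass. Tlr3, a receptor for double-stranded RNA, rose from 5.15 ± 0.1 to 22.2 ± 0.995 FPKM, and Rela, the p65 subunit of NF-kB, rose by 1.00 on the log2 scale. The list was not called (adjusted p = 0.614). Of 12 tested cytosolic DNA sensing genes, 8 rose, 2 fell and 2 did not pass. Those that rose included Zbp1 (4.43) and the neighbouring paralogs Ifi204 (1.61) and Ifi203 (0.97, all log2 fold changes), whose reads can be shared. The DNA sensing list was not called (adjusted p = 0.0536), and rescaling to TPM took it past the threshold (adjusted p = 0.0439). These lists overlap: Zbp1 and Ifi204 are also interferon-stimulated list members, and Zbp1 is in the pyroptosis and necroptosis list. Irf7, the largest rise of the TLR7 and TLR8 pathway list (4.48), is in the interferon-stimulated list too.

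More antigen presentation and inflammatory genes rose than fell. Of 22 MHC class I presentation genes, 18 rose, 3 fell and 1 did not pass: B2m, the shared light chain of MHC class I, rose from 788 ± 7.28 to 2114 ± 79.2 FPKM and H2-Q4, a member of a family of close paralogs, from 104 ± 1.9 to 278 ± 8.02 FPKM. The list was called (adjusted p = 4.32e-05), but not with an estimated correlation (adjusted p = 0.151 with an estimated correlation). Of 31 NF-kB and inflammatory cytokine genes, 21 rose, 7 fell and 3 did not pass. Ptgs2, the inducible cyclooxygenase, rose by 2.03, Lif by 1.77 and Tnfaip3, a feedback inhibitor of NF-kB, by 2.40 on the log2 scale. This list was called (adjusted p = 0.00555), without the call at adjusted p = 0.208 with an estimated correlation or once the trend with genomic span and exonic length was removed (adjusted p = 0.341). Of 9 tested immune checkpoint ligands, 4 rose, 4 fell and 1 did not pass; Lgals9 rose by 1.41 and Pvr by 1.02 on the log2 scale, Nt5e fell by 1.08, and the list was not called (adjusted p = 0.846). Cd274, which encodes PD-L1, rose from 1.79 ± 0.169 to 6.2 ± 0.495 FPKM (log2 fold change 1.36, adjusted p = 7.53e-08, limma).

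Of 20 macrophage and myeloid markers, 16 stayed under 1 FPKM in every library, and the median of their means was 0.00898 FPKM with PBS and 0.228 FPKM with nanoparticles. Of the 4 tested, 3 rose and 1 fell: Cd68, a lysosomal protein also made outside macrophages, rose from 12.2 ± 1.82 to 35.3 ± 1.56 FPKM, Mpeg1 from 0.0824 ± 0.076 to 1.77 ± 0.104 FPKM and Csf1r from 0.0416 ± 0.013 to 1.45 ± 0.36 FPKM. Mpeg1 and Csf1r were under 1 FPKM in every PBS library, so the filter fixed their direction. Of 17 lymphocyte markers in the table, 16 stayed under 1 FPKM in every library, with a median of 0 FPKM in PBS and 0.0951 FPKM in nanoparticle libraries; Lck, the only one tested, rose from 1.08 ± 0.1 to 1.77 ± 0.26 FPKM.

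Of 33 tested immediate early and short-lived transcription factor genes, 31 rose, 24 of them at least 2-fold, and 2 fell (Klf2 at -0.30 and Id3 at -0.21 on the log2 scale, named after their values were seen). The median log2 fold change was 2.11. Egr1 rose from 3.23 ± 0.124 to 92.6 ± 3.73 FPKM and Dusp1, a phosphatase that switches off MAP kinases, from 15.9 ± 0.286 to 146 ± 0.699 FPKM. The list was called (adjusted p = 7.31e-11), but not with an estimated correlation (adjusted p = 0.126 with an estimated correlation). The median genomic span of its members was 5.26 kb.

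Stress genes went in both directions. Of 27 ATF4 integrated stress response genes, 8 rose, 17 fell and 2 did not pass. Ddit3, which encodes CHOP, rose from 30.8 ± 0.663 to 321 ± 5.56 FPKM and Atf3 from 13.9 ± 0.429 to 155 ± 6.97 FPKM, while Asns, the asparagine synthetase, fell from 277 ± 1.94 to 56.8 ± 1.41 FPKM. The list was not called (adjusted p = 0.15), and was called as lower with the trend with span and length removed (adjusted p = 0.0155) or with no filter on low values (0.00893). Of 20 endoplasmic reticulum chaperone genes, 11 rose, 7 fell and 2 did not pass: Hspa5 (BiP) rose from 718 ± 7.95 to 1713 ± 7.06 FPKM and Calr (calreticulin) from 277 ± 4.85 to 789 ± 17.5 FPKM, and Xbp1 fell by 2.19 on the log2 scale. That list was not called (adjusted p = 0.261). Of 17 heat shock and chaperone genes, 13 rose, 3 fell and 1 did not pass; the smallest adjusted p were those of Hspa1b (log2 fold change 2.77, with a near-identical copy, Hspa1a), Hsp90aa1 (1.42) and Hspd1 (0.96), and the list was called (adjusted p = 0.00388; adjusted p = 0.126 with an estimated correlation). Of 26 NRF2 antioxidant genes, 11 rose, 11 fell and 4 did not pass; Gpx1 rose by 2.22, Mgst1 fell by 1.79 and Slc7a11 fell by 3.40, with no call (adjusted p = 0.781).

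More genes of proliferation rose than fell. Of 41 G1/S and DNA replication genes, 35 rose, 3 fell and 3 did not pass, with Cdc6, a loader of the replicative helicase, going from 9.22 ± 0.129 to 45.8 ± 0.892 FPKM and Rrm2, a subunit of ribonucleotide reductase, from 62.4 ± 2.03 to 205 ± 2.37 FPKM (list adjusted p = 7.32e-07; adjusted p = 0.194 with an estimated correlation). Of 40 G2/M and mitosis genes, 32 rose, 5 fell and 3 did not pass, with Aurka rising by 1.86, Cdc20 by 1.89 and Mki67 by 0.43 on the log2 scale (list adjusted p = 1.21e-05; adjusted p = 0.126 with an estimated correlation). Of 43 tested replication-dependent histone genes, 41 rose, 37 of them at least 2-fold, 1 fell and 1 did not pass (H1f2 at -0.45 and H4c12 at 0.50, named after their values were seen). H2ac25 rose from 2.68 ± 0.219 to 21.5 ± 1.23 FPKM. The histone list was called (adjusted p = 1.23e-08) and also with an estimated correlation (adjusted p = 0.0361 with an estimated correlation). Members under 1 FPKM in every PBS library passed the filter only through the nanoparticle libraries, so they could only rise (H3c4 from 0.363 to 6.03 FPKM, H2bc9 from 0.24 to 5.73 FPKM). The camera call weakened to adjusted p = 0.00278, 0.00314 and 0.00487 without nanoparticle library 1, 2 or 3, and to 0.00696 with the filter at 5 FPKM. With no filter on low values it was 4.52e-07. The histone genes are close copies whose transcripts mostly lack a poly(A) tail, so single values are uncertain after mRNA enrichment.

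Of 32 homologous recombination and damage signalling genes, 19 rose, 6 fell and 7 did not pass: Rpa2 rose by 1.74, Fanca by 1.67 and Rad51ap1 by 1.39 on the log2 scale. The list was called at the edge of the threshold (adjusted p = 0.0492; adjusted p = 0.194 with an estimated correlation), and the call was lost with a replicate block (0.0508), without PBS library 1 (0.063), PBS library 2 (0.0654) or PBS library 3 (0.0609), on the TPM scale (0.0624) and with no filter on low values (0.243), but was kept, at adjusted p = 0.000315, with the span and length trend removed. Of 14 non-homologous end joining genes, 6 rose, 7 fell and 1 did not pass. Xrcc1 rose by 0.86, while Xrcc4 (span 316 kb) fell by 1.44 and Xrcc5 (87.5 kb) fell by 0.54, and Xrcc4 no longer passed and Xrcc5 was higher once the trend with span and length was removed. That list was not called (adjusted p = 0.88).

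Among 24 p53 target genes, 10 rose, 11 fell and 3 did not pass, and the list was not called (adjusted p = 0.614). Cdkn1a, Btg2 and Plk2 were the members with the smallest adjusted p, rising by 3.60, 4.77 and 3.15 on the log2 scale. Mdm2, the p53 ubiquitin ligase, rose from 18.4 ± 0.495 to 24.7 ± 1.14 FPKM and Trp53 itself from 28 ± 1.34 to 37.5 ± 1.89 FPKM. Of 27 BCL2 family and caspase genes, 9 rose, 13 fell and 5 did not pass. Cycs, which encodes cytochrome c, rose by 2.71, the survival gene Mcl1 rose by 0.83 and Bcl2 (176 kb) fell by 1.87; the list was not called (adjusted p = 0.866). Of 10 pyroptosis and necroptosis genes, 4 rose and 6 fell, with log2 fold changes of 1.04 for Casp4 and -0.79 for Gsdme, a gasdermin, and no call (adjusted p = 0.984). Hmgb1, released by dying cells, had a log2 fold change of 0.14 that did not pass (28.7 ± 2.27 and 31.8 ± 2.53 FPKM, adjusted p = 0.0738, limma); it passed as higher with a replicate block, without PBS library 3, without nanoparticle library 1, with median-of-ratios scaling and with the span and length trend removed.

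The targets of doxorubicin differed from each other. Top2a stood at 202 ± 2.08 FPKM with PBS and 198 ± 1.36 FPKM with nanoparticles, a log2 fold change of -0.03 that did not pass (adjusted p = 0.216, limma) except on the TPM scale, where it was -0.19. Top2b (70.3 kb, chromosome 14, 16365179 to 16435462) fell from 14.6 ± 0.22 to 3 ± 0.071 FPKM. Among drug transporters, Abcb1b rose from 12.3 ± 0.14 to 20.5 ± 0.455 FPKM, Abcb1a was below the level tested (0.329 ± 0.078 and 0.572 ± 0.172 FPKM), Abcc3 fell by 2.42 and Abcc4 fell by 1.68 on the log2 scale. Of 16 tested drug efflux and doxorubicin target genes, 7 rose, 6 fell and 3 did not pass, with no call (adjusted p = 0.927).

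Genes of ribosome assembly, protein breakdown and respiration rose more often than they fell. Of 37 ribosome biogenesis and MYC target genes, 30 rose, 2 fell and 5 did not pass, with Myc going from 47.3 ± 2.16 to 216 ± 5.33 FPKM, Nop56 rising by 1.56 and Nop2 by 1.89 on the log2 scale (list adjusted p = 1.52e-07; adjusted p = 0.126 with an estimated correlation). Of 37 proteasome subunit genes, 30 rose, 6 fell and 1 did not pass, with Psmc5 up by 1.33 and Psmd4 by 1.24 (list adjusted p = 2.09e-05; adjusted p = 0.194 with an estimated correlation). Of 88 nuclear-encoded oxidative phosphorylation genes, 67 rose, 18 fell and 3 did not pass, with Atp5mc1 up by 1.67 and Ndufa1 by 1.43 (list adjusted p = 1.21e-05; adjusted p = 0.347 with an estimated correlation; 0.14 with the span and length trend removed). Of 13 mitochondrially encoded genes, 8 rose, 1 fell and 4 did not pass, mt-Co1 rising by 0.56, and of 78 cytosolic ribosomal protein genes 37 rose, 18 fell and 23 did not pass, with log2 fold changes of 1.18 for Rplp1 and -0.75 for Rpl10a. Neither was called (adjusted p = 0.116 and 0.0771), although the ribosomal list passed as higher without nanoparticle library 1 (0.0309), without nanoparticle library 2 (0.0387) and with median-of-ratios scaling (0.026). With the span and length trend removed, both lists were called as lower (adjusted p = 0.0106 and 3.74e-05).

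Of 28 hypoxia and glycolysis genes, 9 rose, 18 fell and 1 did not pass: Egln3, an oxygen-sensing prolyl hydroxylase, fell from 69.1 ± 0.363 to 21.3 ± 0.287 FPKM, Ero1a fell by 1.66 and Pfkp fell by 1.48 on the log2 scale. The list was not called (adjusted p = 0.164), and was called as lower with the span and length trend removed (adjusted p = 0.0347) or with no filter on low values (0.00581). Of 24 cholesterol biosynthesis genes, 10 rose, 10 fell and 4 did not pass, with log2 fold changes of 1.23 for Hsd17b7 and -0.92 for Pmvk (list adjusted p = 0.927). Of 34 lysosome and autophagy genes, 17 rose, 10 fell and 7 did not pass, with log2 fold changes of 0.60 for Lamp1, 0.64 for Map1lc3b and -1.85 for Uvrag, which spans 256 kb (list adjusted p = 0.373).

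Of 22 tested senescence-associated secreted genes, 16 rose, 4 fell and 2 did not pass. Areg, a ligand of the EGF receptor, rose from 6.8 ± 0.202 to 151 ± 3.56 FPKM, Plaur by 2.56 and Mmp10 by 2.16 on the log2 scale. The list was called (adjusted p = 0.00526), but not at adjusted p = 0.126 with an estimated correlation or with the span and length trend removed (0.122). Of 19 YAP/TEAD and TGF-beta target genes, 11 rose, 7 fell and 1 did not pass, with log2 fold changes of 2.64 for Ccn1 and -1.82 for Col4a2, which spans 136 kb (list adjusted p = 0.233). Of 13 epithelial genes, 9 rose, 3 fell and 1 did not pass, with log2 fold changes of 2.70 for Elf3, 0.67 for Krt8 and -1.73 for Tjp1, which spans 232 kb (list adjusted p = 0.162). Of 17 mesenchymal transition genes, 8 rose, 7 fell and 2 did not pass, with log2 fold changes of 1.19 for S100a4, -1.97 for Itgb3 and -0.67 for Mmp9 (list adjusted p = 0.614).

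Of the genes listed as fibroblast markers, the 5 that 4T1 cells expressed at a tested level, among them Pdgfra, Pdgfrb and Col6a1, all fell (Pdgfra from 20.5 ± 0.255 to 4.76 ± 0.344 FPKM), and the list was called as lower (adjusted p = 0.0106; adjusted p = 0.285 with an estimated correlation; 0.0669 with the span and length trend removed and 0.57 with no filter on low values). The other 10 stayed under 1 FPKM in every library, and over all 15 the median of the means was 0.0042 FPKM with PBS and 0.191 FPKM with nanoparticles. Of 4 tested endothelial markers, 3 fell and 1 did not pass, with log2 fold changes of -1.89 for Cdh5 and -0.37 for Eng, while 9 of 13 stayed under 1 FPKM (median 0.0419 and 0.234 FPKM). Of 15 erythroid and platelet markers, 13 stayed under 1 FPKM (median 0.0169 and 0.129 FPKM). Both tested members, Slc4a1 and Ppbp, rose, to 1.42 ± 0.104 and 2.05 ± 0.18 FPKM. Slc4a1 was under 1 FPKM in every PBS library, so the filter fixed its direction. Ppbp did not pass once the span and length trend was removed.

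**Figure D2:**
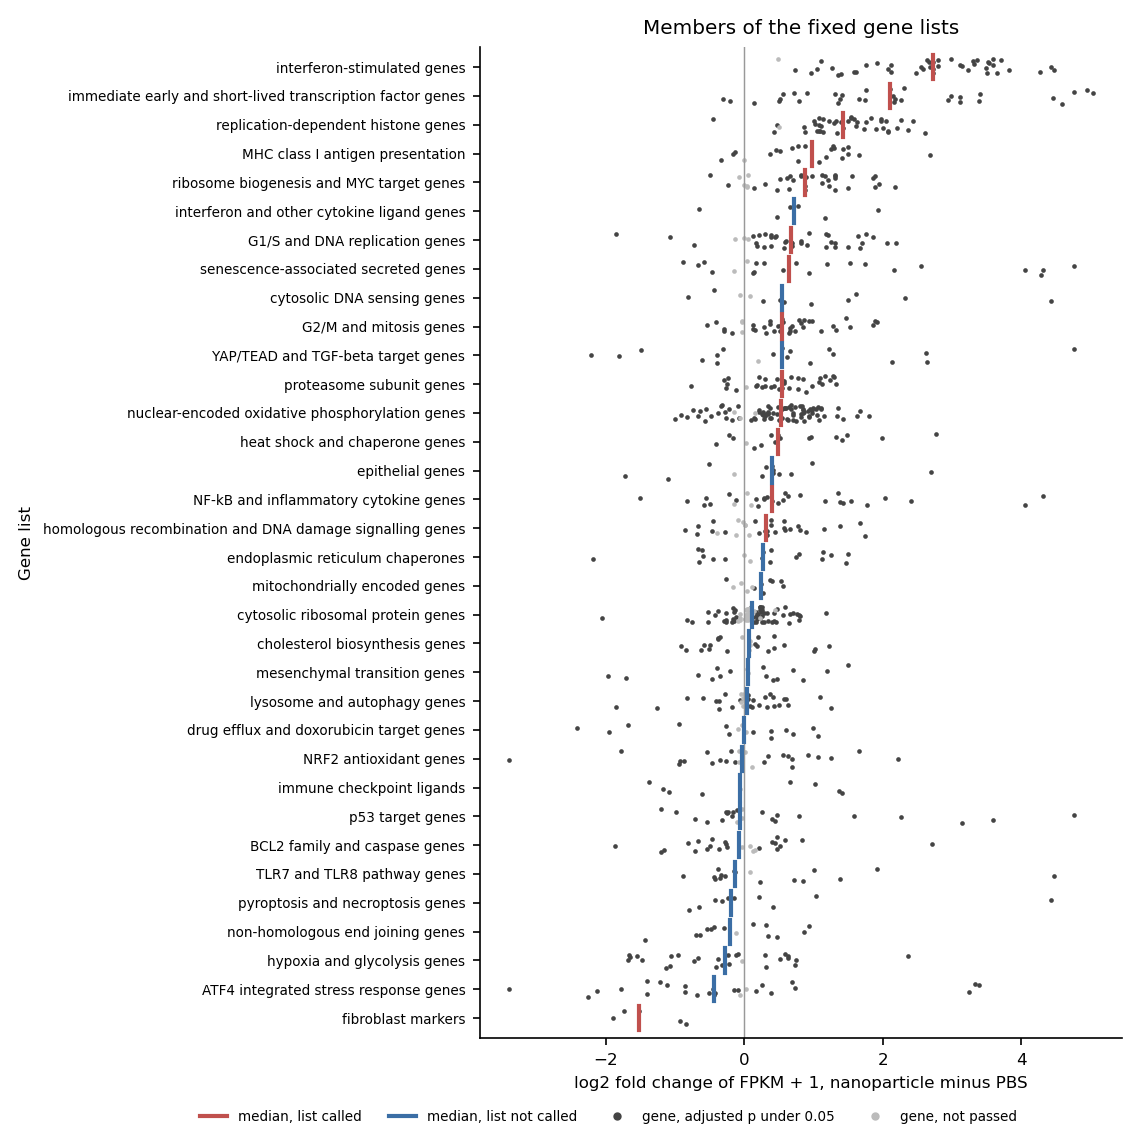
log2 fold change of FPKM + 1 (nanoparticle minus PBS) of every tested member of the 34 tested gene lists, with 1 point per gene (dark where the adjusted p passed, pale where it did not) and a bar at each list's median (red where camera called the list, blue where it did not). Interferon-stimulated genes stand highest with a median of 2.73, fibroblast markers lowest with a median of -1.52, and the median changes sign with the scaling for 7 lists that were not called.

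By limma with Benjamini-Hochberg adjustment, 9391 of 10863 genes changed, 4395 higher and 4996 lower, of which 1104 were higher and 1469 lower by at least 2-fold. Tested against a 1.5-fold change, 4194 genes passed, 1853 higher and 2341 lower. Of the 34 lists, 14 were called, 13 as higher and 1 as lower, and 2 held with an estimated correlation (interferon-stimulated genes and replication-dependent histones). Counts adjusted over the list alone were the same in 36 of the 38 lists; they were 8 rose and 9 fell in the TLR7 and TLR8 pathway list, and 17 rose and 9 fell in the lysosome and autophagy list. Median, mean and test differed in sign in the p53 target, TLR7 and TLR8 pathway, immune checkpoint, pyroptosis and necroptosis, NRF2 and drug efflux lists. The median log2 fold change of all genes was -0.06, and rescaling to TPM moved it to -0.19, so changes of that size depend on the scaling. With no filter on low values, 8445 genes were higher and 5227 lower.

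The change was graded by genomic span, a property examined after the data were seen. Genes under 10 kb had a median log2 fold change of 0.34, and 1600 of 2658 rose while 682 fell. The median was 0.17 for 3736 genes of 10 to 30 kb, -0.34 for 3240 genes of 30 to 100 kb and -1.06 for 1049 genes of 100 to 300 kb. Of 153 genes over 300 kb, 147 fell and 3 rose, with a median of -1.42, and 108 of them fell at least 2-fold. Across 10836 genes, which are not independent replicates, Spearman's correlation of fold change with span was -0.49; between libraries of the same group it lay between -0.07 and 0.12.

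**Figure D3:**
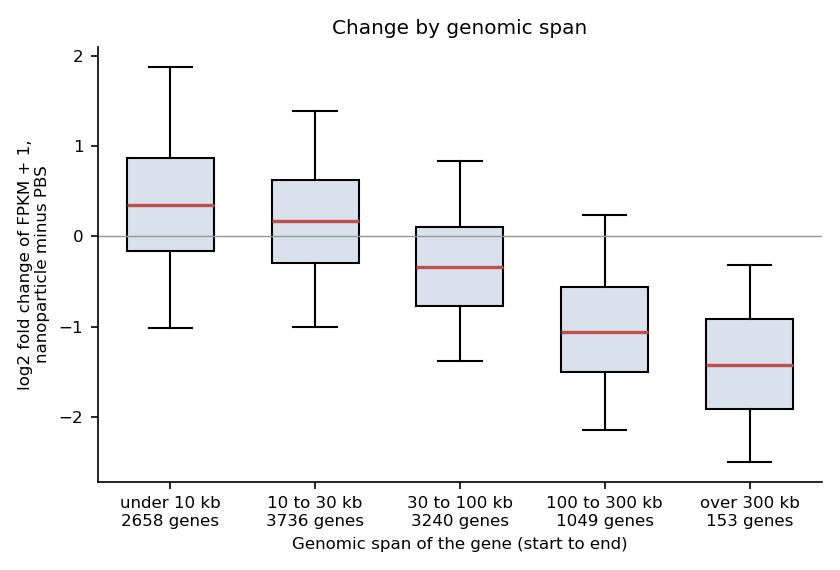
log2 fold change of FPKM + 1 (nanoparticle minus PBS) of tested genes in 5 classes of genomic span (boxes from the lower to the upper quartile, red line at the median, whiskers from the lowest to the highest 5% of genes). Medians run from 0.34 under 10 kb to -1.42 over 300 kb.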

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

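The tests of sequencing depth and of olfactory receptor genes by position were chosen after the result was seen; those of genomic DNA and of neighbouring transcription were set before the values they measure were seen, except that the demand that a ratio by position hold without the 5 gene families was added after that ratio was seen.

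Olfactory receptor genes, which serve the sensory neurons of the nose and which the filter on low values kept out of the main test, stood above their level in the control libraries: of 1193 such genes, 37.7 ± 1.53 were listed above 0 in the PBS libraries and 553 ± 12.7 in the nanoparticle libraries (n = 3 each), at a mean of 0.00194 ± 0.000152 and 0.0291 ± 0.0019 FPKM. Deeper sequencing alone is argued against by the ratio of these means, 15.0, since depth changes how many genes are above 0 and not the mean of a value scaled by depth. Genomic DNA in the treated libraries stays open: it should raise all silent families alike, and relative to olfactory receptors the gains were 0.878 (vomeronasal receptors), 1.17 (keratin-associated proteins), 2.71 (beta-defensins) and 0.282 (bitter taste receptors), of which the last 2 lie outside the range of 0.5 to 2 expected of genomic DNA, but short of the bounds of 0.25 and 4 set for excluding it. The vomeronasal and beta-defensin families were not wholly silent, with highest values of 3.06 and 2.40 FPKM in any library. Vmn2r3 and Defb25, named after their values were seen, were tested (log2 fold changes 1.96 and 0.79). The gains of these 2 families thus rest in part on expressed genes, and were not computed without them. Transcription running on from active neighbours may contribute. Silent genes were here those listed at 0 in every PBS library, so their gain is the nanoparticle mean and cannot be negative. Those within 50 kb downstream of an expressed gene gained 2.40 times as much as those over 200 kb away. This ratio passed the bound of 2 set for running on and against genomic DNA. But 996 of the 2611 distant genes belong to these 5 families of close copies. Without the families, a check added afterwards, the ratio was 1.84 (1.77 to 1.87 per library), so that bound is not taken to decide. Among olfactory receptor genes alone, which were not selected to be at 0 with PBS, the ratio was 1.02 (0.427 to 1.4 per library, only 23 genes close to an expressed gene). For olfactory receptor genes the 2 sources and an effect of the treatment therefore cannot be told apart.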

How the results depend on the processing

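The test with genomic span and exonic length trends removed was chosen after the results were seen, as were the TPM, median-of-ratios and 5 FPKM settings and the inclusion of unnamed features. No scaling, filter, pseudocount, threshold of 0.01, mitochondrial, left-out library or unnamed-feature setting moved the counts of changed genes by over 1.5 times except no filter, which gave 8445 higher genes by testing 20124 in place of 10863. With the trend removed, 1690 genes changed at least 2-fold, 800 of them lower, and 7277 of 8077 genes called both ways kept their direction. Against a 1.5-fold change 4194 genes passed. Lists called numbered 2 with an estimated correlation and 32 with fry, which does not compare a list with other genes. Directions that reversed with the trend removed were Xrcc5 (0.15), mt-Nd6 (-0.26), mt-Co3 (-0.27), the mitochondrially encoded list (adjusted p = 0.0106, range over the alternatives 0.00712 to 0.786) and the cytosolic ribosomal list (3.74e-05, up to 0.859). No other named gene passed in opposite directions; Hmgb1 on the TPM scale and Top2a with median-of-ratios scaling changed sign without passing either way. With fry, the pyroptosis (4.47e-06, up to 0.986), drug efflux (5.85e-05, up to 0.984) and cholesterol (0.00954, up to 0.985) lists reversed; the cause was not tested. Same-numbered libraries showed no sign of deviating together (r = -0.014, -0.043 and 0.041, against -0.077 to 0.094 for differently numbered ones). Residual noise could hide a pairing. A replicate block gave 9371 changed genes. Count-based alternatives (other edgeR normalizations, filterByExpr, DESeq2, limma-voom) were not run, since no counts were used. Unknown depth limits what low values can show.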

Other observations

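All tests of the interferon-stimulated gene pattern below were chosen after the result was seen; those of transcript length, genomic span and GC content, and the splits of the libraries, were set before the values they measure were seen.

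Short genes were higher and long genes lower in the nanoparticle libraries. The Spearman correlation of fold change with exonic length across genes was -0.338. With genomic span held constant it was -0.016 (-0.03 to -0.0034 over the 9 pairs of libraries), which argues against annotated exonic length as such. That length joins the exons of all annotated transcripts of a gene and may differ from the transcripts present in these cells. An effect of transcript length through RNA integrity or fragment size is therefore not excluded. GC content is argued against too, since holding it constant left the correlation with exonic length at -0.326. It also left the correlation with genomic span at -0.49 (-0.496 to -0.479 over the 9 pairs). With exonic length held constant, the correlation with genomic span was -0.381 (-0.382 to -0.371 over the 9 pairs). A candidate explanation is that transcripts from genes with long introns are made less or lost sooner after exposure to an intercalating topoisomerase II poison, a hypothesis that the lack of single-drug and empty-particle groups leaves untested.

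Interferon-stimulated genes were higher in cells whose Tlr7 and Tlr8 transcripts were near the floor. Immune cells as the main source of these transcripts are argued against. The median gain of 37 myeloid and lymphocyte markers was at most 0.00302 of the median gain of the 46 interferon-stimulated genes in any nanoparticle library. This ratio cannot tell whether a few immune cells were present and acted on the tumour cells. The raised level of silent genes is argued against as well: the median gain of the interferon-stimulated genes was at least 1474 times the mean gain of olfactory receptor genes. A response of the tumour cells themselves may remain, through a route these data do not show, and which component of the particles it would answer to was not tested.

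The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9391 changed genes, 4395 higher, 4996 lower and 2573 changed at least 2-fold; the highest of the other splits gave 1 for each of these, so 1 split of 10, the real one, reached each count. For lists called, 5 of the 10 splits gave as many as the real 14, and the highest of the others gave 14. Every other split puts libraries of both treatments in both groups. The treatment difference then becomes spread within groups, so low gene counts in those splits were fixed in advance. Part of that difference also stays between the groups of such a split, so the list counts do not measure chance either. No conclusion is drawn from the splits.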
